A study of Mus musculus with 12 samples.

How the data were processed

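Bulk RNA-seq was deposited for 12 spinal cord libraries of mice, 3 groups of 4: uninjured, injured with vehicle and injured with tamoxifen. Per the submitters' processing notes, reads were processed on mm9 with TopHat, Picard, Cufflinks and HTSeq; the versions and roles of these tools, the strandedness, the read length and the handling of reads with several matches are not given in the sources used here. The authors deposited a table of raw counts for 37991 Ensembl genes, checked to hold whole numbers, and a table of FPKM values (fragments per kilobase of transcript, scaled by library depth). The counts were used for every comparison, and the authors' FPKM only for alternatives and for a test of how libraries were counted. Gene symbols came from the FPKM table for 37818 identifiers and from the reference annotation for 99; 18 identifiers had more than 1 FPKM entry and 22 FPKM cells held no number. The reference annotation is on GRCm38, a later build than mm9, so it was used for names alone and no positions are given. Library totals ran from 7967970 to 12581324 counts. Reads carry no molecular identifiers, so counting errors cover sampling alone.

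Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group at its defaults (minimum count 10, minimum total 15) left 16473 genes, TMM factors scaled the libraries, and 1 quasi-likelihood fit of 3 group means (9 residual degrees of freedom) gave the contrasts, two-sided. The p-values were adjusted by Benjamini-Hochberg over all genes tested at a threshold of 0.05. Levels are TMM-normalised counts-per-million (CPM), mean ± SD of 4 libraries. On simulated data, 50 genes at each fold were recovered for 94%, 78%, 84% and 98% at true folds of 0.25, 0.5, 2 and 4 in vehicle against uninjured, with 14 false calls among 16253 unchanged genes. For tamoxifen against vehicle these were 94%, 78%, 80% and 96% with 10 false calls, and for tamoxifen against uninjured 86%, 72%, 78% and 98% with 7.

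Before the data were examined, 34 gene lists of matrix, cell types and pathways were fixed, of which 32 were tested as sets with camera (limma 3.58.1), at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg over the lists; the line's alleles and the sex-linked genes were read gene by gene. Each list's count of members past the gene test is given over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were run beside it. Of the listed genes, 11 stand in more than 1 list, such as Mmp12 and Egr2. Several lists had median, mean and camera directions of different sign, all with no camera call: ERK pathway genes in vehicle against uninjured, and ERK, proteoglycan and interferon genes in tamoxifen against vehicle, and neutrophil genes in tamoxifen against uninjured.

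The genes named were set by a rule fixed at the same time. In each comparison these are the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap and whose higher mean was at least 5 CPM, up to 4 members with the smallest p of each list described, and 12 fixed genes whatever their values; unnamed or predicted genes and genes with near-identical copies may be left as numbers, and 2 genes under this rule are not reported here. Because the counts of many of the largest rises after tamoxifen stepped, Pdyn, Gabra4 and Arxes1 were named after their values were seen, from the largest rises without stepped genes.

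The sex of each mouse was read from Xist, Ddx3y, Kdm5d, Uty and Eif2s3y, giving 4 male and 8 female libraries. Stepped genes were those whose log2 ratio of CPM to FPKM (0.1 and 0.01 added), centred on each library's median, differed by more than 0.5 on average between the 3 libraries with sample names 106 to 108 and the 9 others, with no overlap between them, among genes with at least 200 counts in total. A simulated 2-fold step was found in 88 of 95 genes. Its 0 false calls give no error rate, since the simulation filled the 3 libraries with copies of others. Unchanged genes therefore overlapped by construction. The skeletal muscle score is the mean log2 CPM of its list, and libraries above 2 were called high in muscle transcripts. Reversal was read from the sign of the tamoxifen change over the genes called after injury, with the vehicle libraries split in all 6 ways and in 20 simulations without a tamoxifen effect. The share of sequence common to other genes was read from 31-base words of the reference transcripts, 1 in 16 of them kept, for genes with at least 10 such words.

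Alternatives planned before the data were examined were DESeq2 size factors, library totals alone, no filter or a stricter one (1 CPM in at least 8 libraries), the DESeq2 1.42.0 Wald test, limma-voom, limma on log2 FPKM with 1 or 0.1 added, a fit of the 8 libraries compared, thinning to the smallest library, terms for sex and for the sample name series, a fold of at least 2, each library left out in turn, and for lists fry, an estimated correlation and each gene in 1 list only. After the data were seen, the low sample name series alone, sex and series terms together, the female libraries, the stepped genes left out, the 5 libraries with muscle transcripts left out and a muscle score term were added. All 35 divisions of the 8 libraries of a comparison into 4 and 4 were tested. No paired analysis was possible because mouse numbers are not shared among the groups.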

Results

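RNA was sequenced from the spinal cord of 12 adult mice (over 8 weeks old, C57bl/6J background) that carried Glast-CreERT2, R26R-YFP and Rasless alleles. In this line, which is used to mark type A pericytes, tamoxifen activates a Cre recombinase expressed from the Glast (Slc1a3) promoter. The labels gave 3 groups of 4 mice: uninjured cord segments, and dorsal hemisection lesions at high thoracic level dissected 14 days after injury from mice that had received vehicle or tamoxifen (2 mg on each of 5 days, then 7 clearing days before surgery). The series described the vehicle lesions as densely scarred and the tamoxifen lesions as scarred less by pericyte-derived cells, so a lower level of scar genes after tamoxifen is not independent of how the lesions were described. Libraries are named by their mouse numbers. Total counts were 8868865 in uninjured library 376, 11686386 in 377, 11366807 in 385 and 11391206 in 467. Vehicle libraries held 9397615 (402), 7967970 (428), 10778041 (429) and 12581324 (457) counts. Tamoxifen libraries held 8302843 (452), 10897192 (513), 11804143 (549) and 10980319 (564) counts.

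Other features of the libraries moved with the groups. The labels' sample names run from 1 to 20 for 9 libraries, 452 included, and from 106 to 108 for 513, 549 and 564. In those 3 libraries, called the high series here, the counts of 497 of 15259 genes compared stepped against the same libraries' FPKM. Of these steps 481 were upward, and the highest number of steps for any other trio of libraries was 70. Of the tamoxifen libraries only 452 belongs to the low series, so a fit with a series term rests the tamoxifen effect on that library. By Xist and Y-linked transcripts, all 4 tamoxifen mice were female, 3 of the 4 vehicle mice were male, and 3 of the 4 uninjured mice were female. Skeletal muscle transcripts had a mean log2 CPM above 2 in vehicle libraries 402 (4.54), 429 (3.97) and 457 (5.57) and in uninjured libraries 377 (5.16) and 385 (3.03), with a highest value of 1.19 among tamoxifen libraries. The first principal component of log2 CPM held 51.4% of the variance and the second 21.9%. On the second, libraries 513, 549 and 564 lay at -45.9, -50.7 and -43.7, apart from tamoxifen library 452 at 2.8. Uninjured and vehicle libraries lay from -4.76 to 42.1 there, so this component separated the high series from all other libraries. Within groups, the median correlation between libraries across genes, which are not independent replicates, was 0.98 in uninjured, 0.98 in vehicle and 0.97 in tamoxifen.

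Genes of the line's alleles were read first. Hras1 (ENSMUSG00000025499) did not pass the test between tamoxifen and vehicle lesions (edgeR quasi-likelihood, log2 -0.02, Benjamini-Hochberg adjusted p = 0.925). Nras (ENSMUSG00000027852) did not either (log2 -0.03, adjusted p = 0.913). Slc1a3 (ENSMUSG00000005360), the glutamate transporter whose promoter drives the Cre, was at 213 CPM ± 19.7 (SD, n = 4) in tamoxifen and 197 ± 11.5 in vehicle lesions (adjusted p = 0.327). With the series term these 3 genes did not pass either. The tissue level covers every cell in the piece, and recombined cells were not measured apart from the others.

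**Figure D1:**
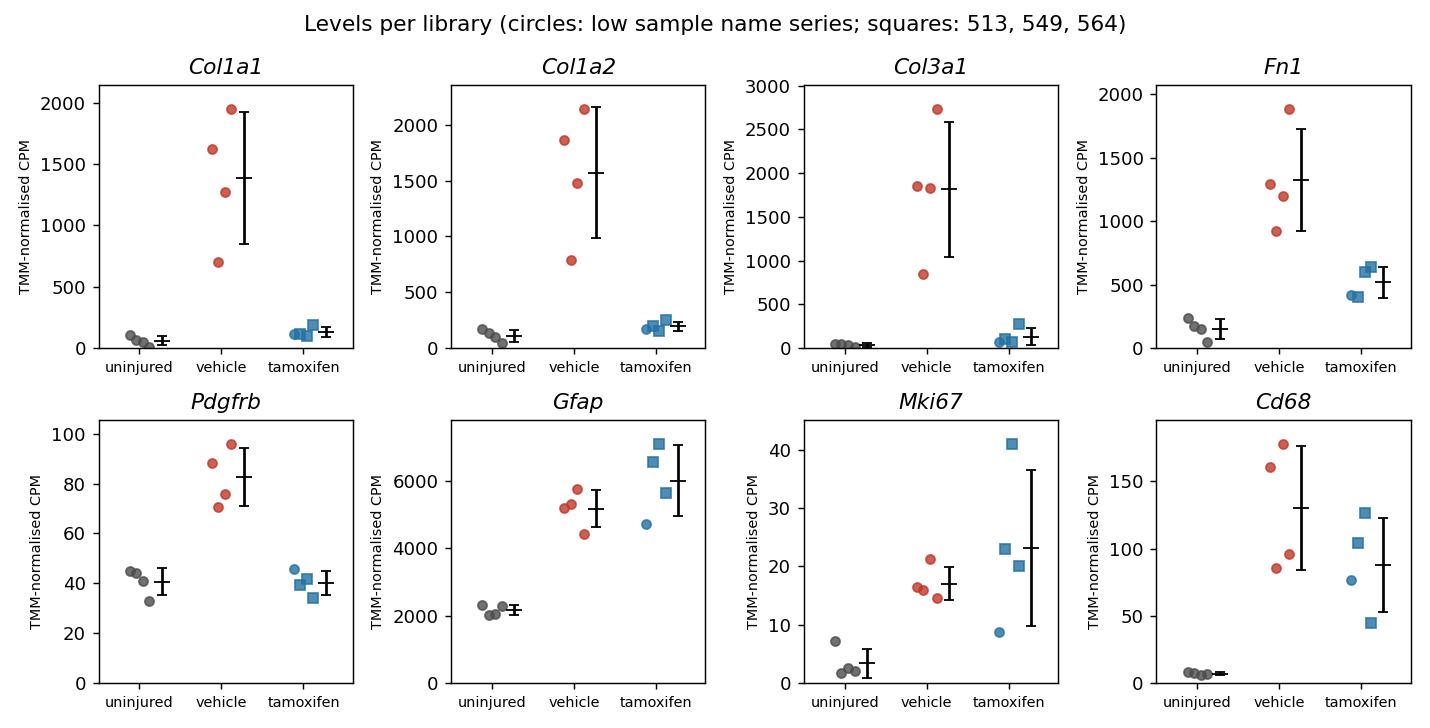
TMM-normalised counts-per-million (CPM) of 8 genes in each library, by group, with the mean and SD of 4 libraries beside the points; circles are the low sample name series and squares libraries 513, 549 and 564. Col1a1 averaged 1386 CPM in vehicle lesions against 129 in tamoxifen lesions, and Cd68 averaged 130 in vehicle lesions against 87.8 in tamoxifen lesions.

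The comparison of vehicle lesions with uninjured cord asked what the injury site expresses while a dense scar is present. Genes of scar matrix rose throughout the list: 24 of 24 measured members rose (24 adjusted over the list alone), with a median log2 change of 3.70. Col1a1 (ENSMUSG00000001506), a chain of type I collagen, stood at 1386 CPM ± 536 (SD, n = 4) in vehicle lesions and 60.3 ± 38.9 in uninjured cord, a 23.1-fold difference (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.78e-05). Col1a2 rose 14.2-fold, Col3a1 of type III collagen 53.1-fold and fibronectin (Fn1) 8.67-fold. Col12a1 rose 13.5-fold and Loxl2, which crosslinks collagen, 12.9-fold. Of 15 basement membrane genes 13 rose (13 adjusted over the list alone), among them Col4a1 (4.68-fold) and the laminin chain Lamc1 (2.46-fold). Of 17 matrix proteases and inhibitors 15 rose (15 adjusted over the list alone), with Timp1, an inhibitor of metalloproteinases, up 27.5-fold. The macrophage metalloelastase Mmp12 was at 25.3 CPM ± 14.8 against 0.0506 ± 0.0595. For scar matrix, basement membrane and proteases, camera's adjusted p was 6.4e-25, 5.96e-14 and 2.04e-10 in that order, and 0.0945, 0.0779 and 0.0945 with an estimated correlation.

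Genes of fibroblasts and mural cells rose with the matrix. Of 17 fibroblast markers 13 rose (13 adjusted over the list alone), with the proteoglycans Lum up 11.7-fold and Dcn 6.80-fold. Of 16 pericyte and smooth muscle markers 11 rose (11 adjusted over the list alone). Pdgfrb, the receptor for PDGF-BB, rose 2.04-fold, Anpep 10.9-fold, Cspg4 2.83-fold and Rgs5 1.43-fold. In the TGF-beta and fibrogenic list 13 of 17 rose (15 adjusted over the list alone), including Tgfb1 (5.24-fold) and the latent TGF-beta binding protein Ltbp2 (30.8 CPM ± 11.5 against 0.283 ± 0.0841). Lrrc15 was at 14.8 CPM ± 10.8 in vehicle lesions and 0.0653 ± 0.0839 in uninjured cord. Ccl21a, a lymphatic chemokine with near-identical copies, was at 10.8 CPM ± 6.29 against 0.0287 ± 0.0574, and Mmrn1, which lymphatic endothelium expresses, at 9.29 ± 5.71 against 0.0861 ± 0.172. The fibroblast, pericyte and TGF-beta lists had camera adjusted p of 0.000384, 0.000384 and 1.31e-09, and 0.447, 0.195 and 0.0779 with an estimated correlation. Skeletal muscle transcripts were high in 3 of the 4 vehicle libraries and 2 of the 4 uninjured ones. Of 12 Schwann cell and nerve root genes 6 rose (6 adjusted over the list alone; camera adjusted p = 0.0379, 0.0884 without library 428, and adjusted p = 0.508 with an estimated correlation).

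Inflammatory and glial genes rose at the lesions. Of 25 macrophage and phagocyte markers 24 rose (24 adjusted over the list alone), with Gpnmb up 117-fold, Itgax 92.7-fold, Lgals3 25.6-fold and the lysosomal protein Cd68 18.8-fold. Cst7 stood at 41.01 CPM ± 22.8 in vehicle lesions against 0.152 ± 0.130 in uninjured cord, Cd22 at 22.9 ± 9.28 against 0.245 ± 0.159, and Atp6v0d2, a subunit of the vacuolar proton pump, at 16.5 ± 9.03 against 0.1002 ± 0.118. All 13 complement genes rose (13 adjusted over the list alone), C1qa 8.21-fold and C4b 4.20-fold. Of 14 cytokines and chemokines 13 rose (14 adjusted over the list alone), including Ccl3 (10.2 CPM ± 3.77 against 0.202 ± 0.176), and 10 of 12 microglia markers rose (10 adjusted over the list alone), including Cx3cr1 (4.18-fold). All 18 reactive astrocyte markers rose (18 adjusted over the list alone). Gfap, the astrocyte intermediate filament, rose 2.39-fold to 5176 CPM ± 550, Vim 9.13-fold and Ptx3 23.6-fold. Camera's adjusted p for the macrophage, complement, cytokine, microglia and reactive astrocyte lists was 6.28e-23, 1.21e-12, 2.98e-07, 9.09e-07 and 2.53e-17, and 0.0779, 0.0779, 0.162, 0.162 and 0.0779 with an estimated correlation. Of 18 interferon-stimulated genes 14 rose and of 14 antigen presentation genes 9 (15 and 9 adjusted over the list alone). Of 24 proliferation genes 19 rose (20 adjusted over the list alone), with Mki67 up 5.33-fold (by 2.41 on the log2 scale, and 3.04 without library 376), Top2a 8.65-fold and Cdk1 7.53-fold. For interferon, antigen presentation and proliferation, adjusted p was 5.28e-05, 0.00024 and 2.03e-05 by camera, and 0.447 for each of them with an estimated correlation.

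Neuronal and cholesterol genes fell. Of 20 measured neuron markers 19 fell (19 adjusted over the list alone), with the nuclear protein Rbfox3 at 98.2 CPM ± 14.7 in vehicle lesions against 202 ± 3.12 and the glutamate transporter Slc17a6 at 131 ± 20.0 against 258 ± 7.14. The NMDA receptor subunit Grin2b fell by 2.10 on the log2 scale, the opioid receptor Oprm1 by 1.78, and the potassium channels Kcnj6 by 1.76 and Kcnh5 by 1.75. Hs6st3 fell by 1.83, Aqp6 by 1.86 and Lgr6 by 1.96. All 19 measured genes of cholesterol synthesis and its control fell (19 adjusted over the list alone), among them Insig1 by 1.09 on the log2 scale. The neuron and cholesterol lists had camera adjusted p of 6.53e-09 and 4.76e-10, and adjusted p of 0.145 and 0.195 with an estimated correlation. Of 13 chondroitin sulphate proteoglycan genes 4 rose and 2 fell, Acan by 0.51 (4 and 1 adjusted over the list alone; camera adjusted p = 0.464). Nras rose 1.47-fold (adjusted p = 0.0212), Slc1a3 rose 1.41-fold, and Hras1 did not pass (log2 -0.17, adjusted p = 0.263). The Nras call was lost without library 376 (adjusted p = 0.0604), 377 (0.066) or 429 (0.101).

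In all, 8368 of 16473 genes tested changed between vehicle lesions and uninjured cord, 4393 higher and 3975 lower (edgeR quasi-likelihood, Benjamini-Hochberg threshold 0.05), and 2052 of them by at least 2-fold. Camera with a preset correlation called 20 of 32 lists, 18 up and 2 down, and none with an estimated correlation. By fry, which does not set a list against the other genes, 25 lists passed, 21 up and 4 down. Other divisions of the same 8 libraries gave up to 24 lists by camera with the preset correlation, so the gene counts above carry the comparison. Without the 5 libraries with muscle transcripts, which leaves 1 vehicle library, 296 genes passed, and 5250 passed in the 8 female libraries, which also leaves 1 vehicle library.

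**Figure D2:**
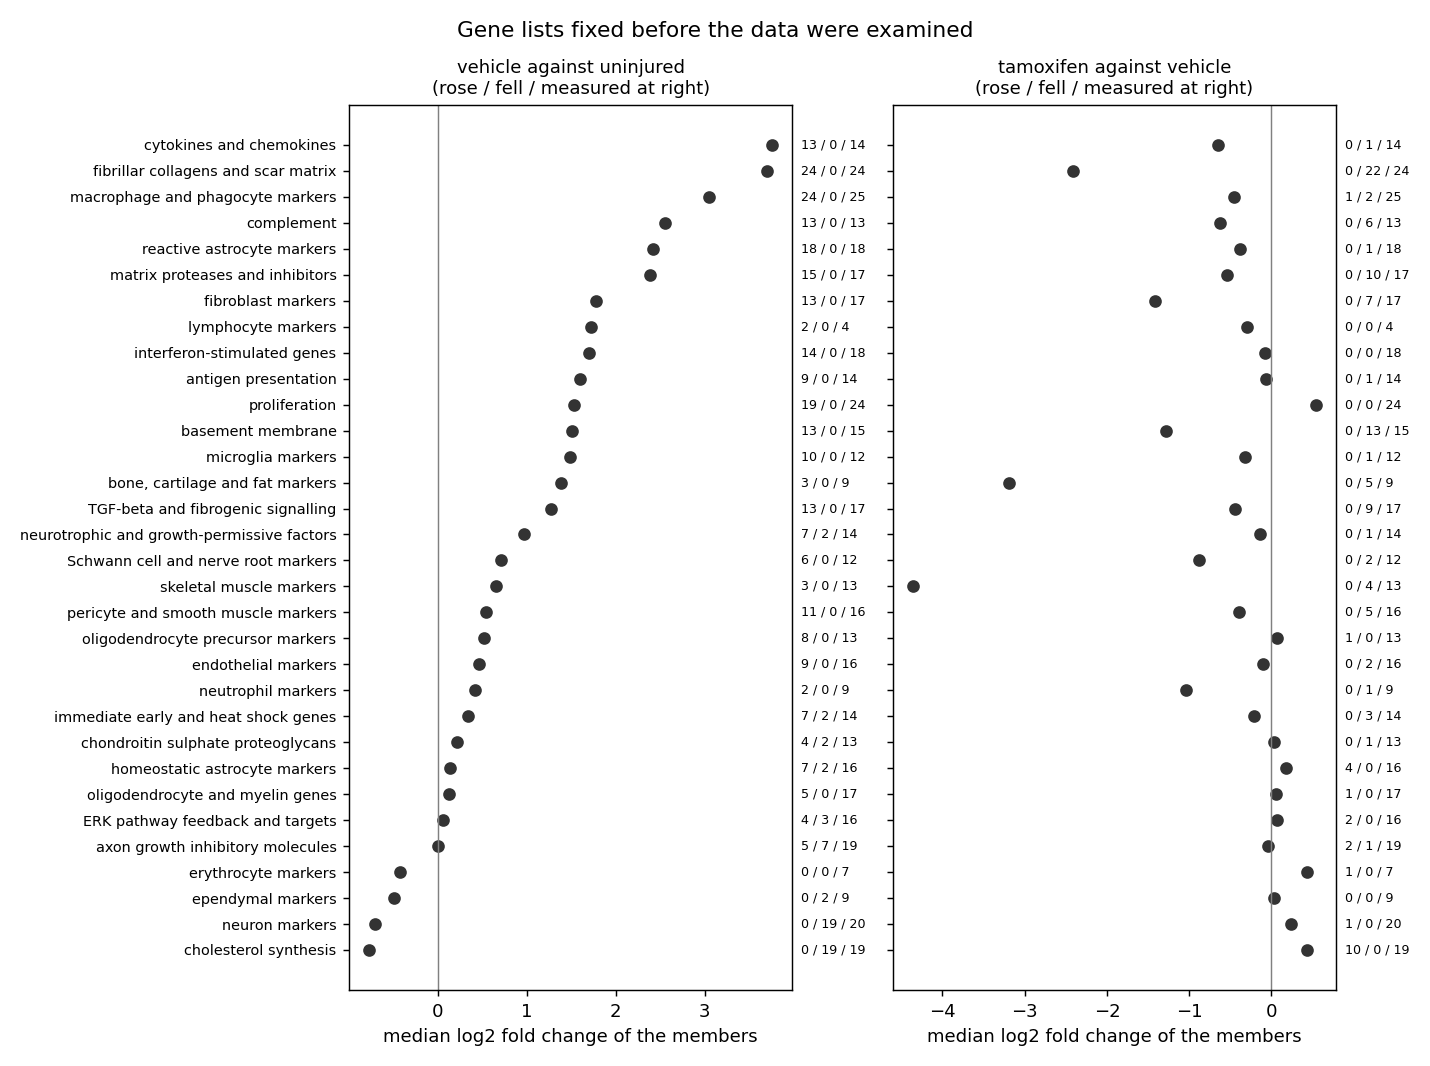
Median log2 fold change of the measured members of each of 32 gene lists (horizontal axis) in vehicle lesions against uninjured cord (left) and tamoxifen against vehicle lesions (right), with the numbers of members that rose, fell and were measured at the right of each panel. The scar matrix list stood at a median of 3.70 on the left and -2.41 on the right.

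The comparison of tamoxifen with vehicle lesions asked how a lesion scarred less by pericyte-derived cells differs from a densely scarred lesion. Scar matrix genes fell: 22 of 24 measured members passed (24 adjusted over the list alone), with a median log2 change of -2.41. Col1a1 stood at 129 CPM ± 39.9 (SD, n = 4) in tamoxifen lesions against 1386 ± 536 in vehicle lesions and fell by 3.42 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0022). Col1a2 fell by 3.02, Col3a1 by 3.79 (4.46 without library 564, and 4.60 with the series term) and Fn1 by 1.36 (adjusted p = 0.071 without library 457 and 0.0784 without 513). The type VI collagen chains Col6a1, Col6a2 and Col6a3 fell by 3.10, 3.16 and 3.65, each with adjusted p = 0.00025. In library 452, the tamoxifen library of the low series, all 24 members lay below every vehicle library. With the series term 8 of 24 fell (median -2.84), and with the sex term 21 fell (median -2.73). With that series term Col1a1 changed by -3.61 (adjusted p = 0.134), and the chain Col6a2 by -3.10 (adjusted p = 0.0427). Camera's adjusted p for the list was 5.82e-43, and adjusted p = 0.0808 with an estimated correlation.

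Other genes of matrix and mural cells fell too. Of 15 basement membrane genes 13 fell (14 adjusted over the list alone), with the laminin chains Lamb1 down by 1.98 and Lamc1 by 1.05 and the collagens Col4a2 by 1.33 and Col15a1 by 2.18 on the log2 scale. This list kept its camera call with an estimated correlation (adjusted p = 0.031 there, 9.26e-33 with the preset), and 5 members fell with the series term and 13 with the sex term. Of 17 matrix proteases and inhibitors 10 fell (10 adjusted over the list alone), with Mmp2 down by 2.79, Mmp12 by 2.52 (1.92 with the series term) and cathepsin K (Ctsk) by 2.33. Of 17 fibrogenic genes 9 fell (12 adjusted over the list alone), Ltbp2 by 3.29 (4.83 with the series term) and Tgfbi by 1.37. Of 17 fibroblast markers 7 fell (10 adjusted over the list alone), Lum by 3.16, Dpt by 3.09 and Mfap5 by 2.77 (3.51 with the series term). Of 16 pericyte and smooth muscle markers 5 fell (7 adjusted over the list alone). Pdgfrb stood at 40.2 CPM ± 4.88 against 82.6 ± 11.6 in vehicle lesions and fell by 1.04 (adjusted p = 0.000736; -0.85 and 0.102 with the series term). Mcam fell by 0.52 and Anpep by 1.40, and Rgs5 was at 181 CPM ± 9.19 in tamoxifen and 180 ± 4.99 in vehicle lesions. With the series term 1 fibrogenic gene, Ltbp2, and no protease, fibroblast or pericyte gene passed, and with the sex term 6 fibrogenic, 8 protease, 6 fibroblast and 3 pericyte genes fell. Camera's adjusted p for proteases, fibrogenic genes, fibroblasts and pericytes was 6.97e-08, 1.19e-07, 5.1e-07 and 0.00187, and 0.229, 0.109, 0.457 and 0.454 with an estimated correlation.

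Markers of neighbouring tissue differed with the scar genes. Of 13 skeletal muscle markers 4 fell (10 adjusted over the list alone), with the myosins Myh1 and Myh2 at 49.4 CPM ± 47.6 and 36.3 ± 29.6 in vehicle lesions against 0.573 ± 0.446 and 0.415 ± 0.384, and myoglobin (Mb) at 24.5 ± 21.8 against 0.994 ± 0.345. Of 9 measured bone, cartilage and fat markers 5 fell (6 adjusted over the list alone), Comp of cartilage by 3.28. Of 12 Schwann cell and nerve root genes 2 fell (4 adjusted over the list alone), with a list median of -0.88 (-0.77 with the series term). Among the largest falls of single genes, Thbs4 fell by 5.69 (5.02 without library 457) and Aspn by 5.00. Tnn stood at 0.436 CPM ± 0.115 in tamoxifen lesions against 15.8 ± 9.87, Lrrc17 at 0.389 ± 0.129 against 10.2 ± 8.10, and Lrrc15 at 0.326 ± 0.223 against 14.8 ± 10.8. Ccl21a was at 0.0300 CPM ± 0.0599 in tamoxifen lesions against 10.8 ± 6.29, and Mmrn1 at 0.0450 ± 0.0520 against 9.29 ± 5.71. The Y-linked Ddx3y was at 0.0230 ± 0.0459 against 73.8 ± 49.0, with 3 male mice among the 4 of the vehicle group, and lost its call without library 402 (adjusted p = 0.0546), 457 (0.0594), 513 (0.0858), 549 (0.0657) or 564 (0.122). The muscle, bone and Schwann lists had camera adjusted p of 0.000204, 0.0102 and 0.0121, and adjusted p of 0.598 for each with an estimated correlation; no member of the 3 lists passed with the series term, and 2, 0 and 1 fell with the sex term. Without library 452 the bone and Schwann lists had camera adjusted p of 0.173 and 0.171.

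Part of the inflammatory response was lower. Of 13 complement genes 6 fell (7 adjusted over the list alone), with C1s at 3.70 CPM ± 0.798 against 16.4 ± 4.89 and C3 at 298 ± 123 against 649 ± 250 in vehicle lesions, where C3 lost its call without library 513 (adjusted p = 0.0579) or 564 (0.0508). Of 25 macrophage and phagocyte markers Itgax and Mmp12 fell and Arg1 rose (2 and 1 adjusted over the list alone), while Cd68 did not pass (log2 -0.57, adjusted p = 0.186). Arg1 changed by 2.43 on the log2 scale, but by 1.60 without library 549 and by -1.36 with the series term, and was at 0.719 CPM in library 452; its call was lost without library 402 (adjusted p = 0.0662), 428 (0.0642), 457 (0.0883), 513 (0.0601), 549 (0.0941) or 564 (0.0629). The neutrophil gene Csf3r fell by 0.85, the microglial Tmem119 by 0.64, Igf1 by 1.44 and Il1rn by 1.77, the members of their lists that fell (1, 1, 0 and 0 adjusted over the list alone). Tmem119 lost its call without library 402 (adjusted p = 0.0585), 429 (0.059), 513 (0.0595) or 564 (0.069). Igf1 lost it without 385 (0.0527), 402 (0.0658), 429 (0.0693), 457 (0.101), 513 (0.0941), 549 (0.0769) or 564 (0.103), and Il1rn without 377 (0.0557), 385 (0.0569), 402 (0.0702), 429 (0.149), 513 (0.113), 549 (0.0767) or 564 (0.107). The macrophage, neutrophil and cytokine lists had camera adjusted p of 0.00351, 0.0235 and 0.0214, each with adjusted p = 0.605 with an estimated correlation, and complement 1.81e-05, with adjusted p = 0.376 with an estimated correlation. Neutrophils had a camera adjusted p of 0.179 without library 452, and cytokines 0.115 without 429 and 0.0678 without 549. With the series term no complement, macrophage, neutrophil, cytokine, microglia or neurotrophic gene passed, and with the sex term 6, 4, 1, 3, 0 and 2 fell. The falls of C3, Itgax and Il1rn, 1.12, 1.51 and 1.77 on the log2 scale, were 0.45, 0.77 and 0.97 with the series term, and that of Il1rn was 1.05 without library 429. Of 18 interferon-stimulated genes none passed and of 14 antigen presentation genes 1 fell (0 and 0 adjusted over the list alone; 3 and 1 rose with the series term, and none passed with the sex term). In library 452 these 2 lists averaged 4.70 and 5.68 on the log2 CPM scale, above every other library, while the high series lay at 3.02 to 3.41 and 3.71 to 4.37. Without that library camera called both lists lower (adjusted p = 0.0178 and 0.0328), while with all libraries and an estimated correlation their adjusted p was 0.863 and 0.837.

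Part of the cholesterol genes and few astrocyte or neuronal genes were higher. Of 19 cholesterol genes 10 rose (15 adjusted over the list alone), with Insig1 up 1.81-fold and Fdft1, squalene synthase, 1.51-fold; 1 member passed with the series term and 16 with the sex term. Of 16 homeostatic astrocyte markers 4 rose (4 adjusted over the list alone), among them the transporter Slc7a10 (1.31-fold) and the gap junction protein Gja1 (1.28-fold), none with the series term and 1 with the sex term. Gja1 lost its call without library 402 (adjusted p = 0.0688), 457 (0.0637), 513 (0.0826) or 549 (0.0592). Of 20 neuron markers 1 rose, Stmn2 (1.21-fold; 1 adjusted over the list alone; 0 with the series term and 0 with the sex term). Camera's adjusted p for cholesterol, homeostatic astrocytes and neurons was 2.15e-09, 0.00572 and 0.00572, and 0.376, 0.598 and 0.598 with an estimated correlation. For homeostatic astrocytes it was 0.052 without library 457 and 0.14 without 452, and for neurons 0.0652 without 429 and 0.316 without 452. Pdyn, the precursor of dynorphin opioid peptides, rose 2.16-fold, Gabra4, a GABA receptor subunit, 1.71-fold and Arxes1 1.68-fold; these 3 were named after their values were seen, since counts of the rule's largest rises stepped. Gfap (log2 0.22, adjusted p = 0.223, but 0.0365 without library 452) and Mki67 (log2 0.45, adjusted p = 0.462) did not pass, and Ptx3 fell by 0.76 (1.54 with the series term), the 1 of 18 reactive astrocyte markers that fell (0 adjusted over the list alone; 1 with the series term and 4 with the sex term; camera adjusted p = 0.0299, and adjusted p = 0.616 with an estimated correlation). That list had a camera adjusted p of 0.175 without library 429 and 0.206 without 452, and Ptx3 lost its call without 402 (adjusted p = 0.0599), 428 (0.0688), 429 (0.0559), 457 (0.0521) or 513 (0.0948). No proliferation gene passed among 24 (0 adjusted over the list alone), and Pcna had an adjusted p of 0.0603 (0.0429 without library 402 and 0.00753 without 452). The proliferation list's camera adjusted p was 0.00432 upward, 0.112 without library 549, 0.625 with an estimated correlation, and its median of 0.54 became -0.73 with the series term. Of 16 genes of the ERK pathway 2 rose, Etv1 1.51-fold (2 rose and 1 fell adjusted over the list alone; 0 with the series term and 1 rose with the sex term). Of 13 proteoglycan genes Acan fell by 0.31 (1 adjusted over the list alone; 0 with the series term and 0 with the sex term), a call lost without library 402 (adjusted p = 0.0532), 457 (0.0575), 513 (0.0519), 549 (0.0533) or 564 (0.0725). The mitochondrial mt-Nd3 and Sumo2 led the rises at 508 CPM ± 338 and 77.8 ± 50.6, but both counts stepped in the high series and were 1.92 and 2.04 in library 452.

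In all, 2655 of 16473 genes changed between tamoxifen and vehicle lesions, 1283 higher and 1372 lower (edgeR quasi-likelihood, Benjamini-Hochberg threshold 0.05), 615 by at least 2-fold; 303 of them had stepped counts, 299 of these higher. The low series alone keeps 1 tamoxifen library and the female libraries keep 1 vehicle library, so fewer calls there also follow from fewer libraries. Fewer genes passed in other fits: the count was 57 with the series term (17 higher, 40 lower), which rests on library 452, and 989 with the sex term. It was 99 with the skeletal muscle score as a term, 204 in female libraries, and 0 without the 5 libraries with muscle transcripts (edgeR; 1239 genes at an unadjusted p under 0.05), which leaves 1 vehicle library. It moved from 1236 without library 513 and 1324 without 564 to 1688 without 457 and 4631 without 452, and camera called 19 of 32 lists (4 up, 15 down), as many as 2 other divisions of the 8 libraries did. By fry 8 lists passed, 1 up and 7 down.

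**Figure D3:**
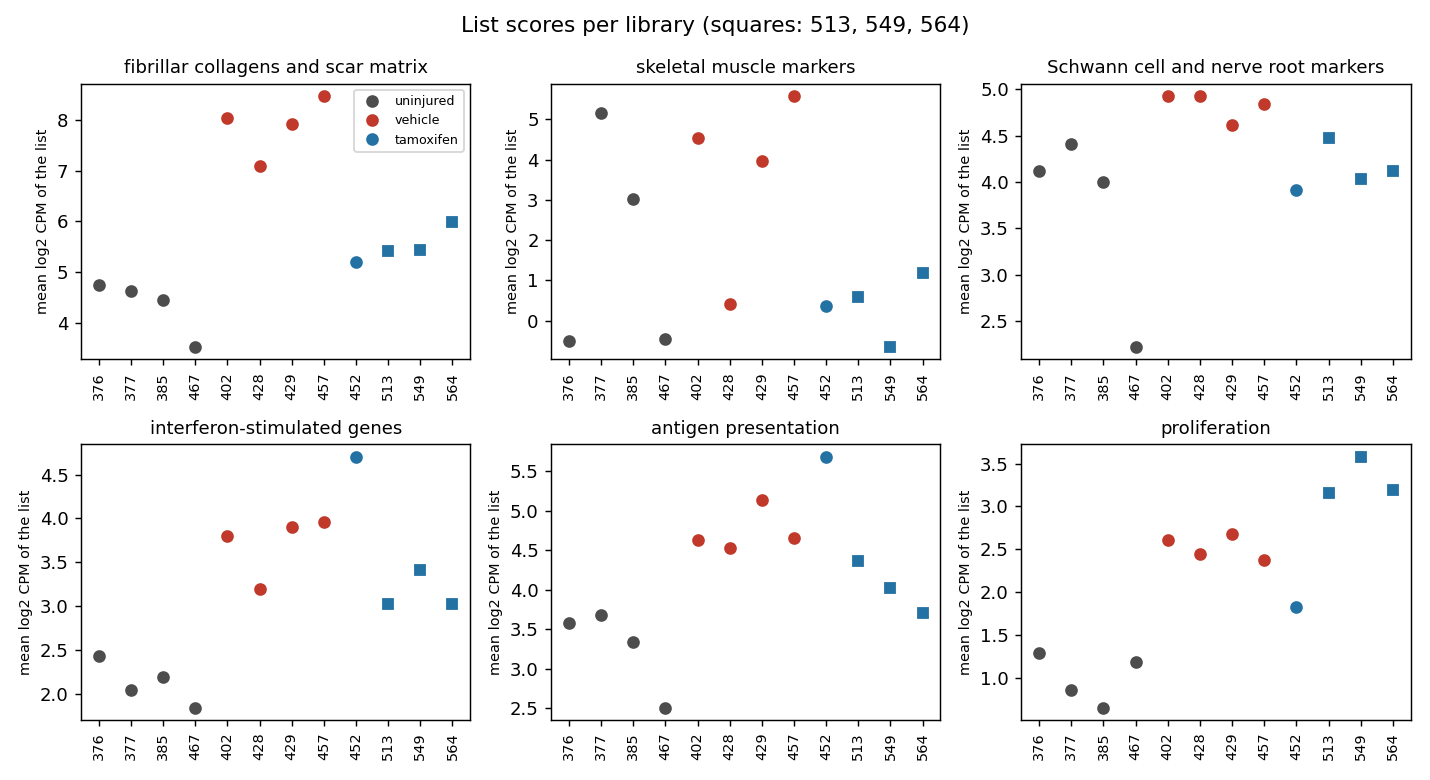
Mean log2 CPM over the members of 6 gene lists in each library, coloured by group; squares are libraries 513, 549 and 564. Interferon-stimulated genes averaged 4.70 in library 452 against 3.02 to 3.41 in the other tamoxifen libraries, and skeletal muscle markers reached 5.57 in vehicle library 457.

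The comparison of tamoxifen lesions with uninjured cord asked what differs from uninjured cord in a lesion scarred less by pericyte-derived cells. The uninjured mice were given no tamoxifen, so injury cannot be told apart here from the drug and recombination. All uninjured libraries belong to the low series, and of the tamoxifen libraries only 452 does. Phagocyte and reactive astrocyte genes were high here too: 23 of 25 macrophage markers and 17 of 18 reactive astrocyte markers rose (23 and 18 adjusted over the list alone). Gpnmb rose 84.7-fold (46.6-fold with the series term), the beta-glucan receptor Clec7a 32.5-fold, Lgals3 18.6-fold and Cd68 12.7-fold. Cst7 averaged 17.6 CPM ± 18.9 against 0.152 ± 0.130, a level that rests on library 452 (45.9 CPM against 7.28 to 8.73 in the high series). Gfap rose 2.78-fold to 6009 CPM ± 1050 (SD, n = 4) and Vim by 2.91 on the log2 scale (2.08 with the series term). With the series term 21 and 15 members of these lists rose, and with the sex term 22 and 18. Of 24 proliferation genes 23 rose (24 adjusted over the list alone; 6 with the series term, 23 with the sex term), with Top2a up by 3.93, Mki67 by 2.87 (3.49 without library 376) and Cdk1 by 3.70 on the log2 scale. These rises were larger in the high series than in library 452, and with the series term they were 2.06, 1.45 (adjusted p = 0.139) and 2.22. Of 13 complement genes 9 rose (12 adjusted over the list alone; 6 with the series term, 9 with the sex term), C1qa 6.55-fold. The macrophage, reactive astrocyte, proliferation and complement lists had camera adjusted p of 3.31e-22, 3.81e-17, 2.34e-10 and 3.74e-08, and adjusted p of 0.165, 0.165, 0.362 and 0.28 with an estimated correlation.

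Scar genes rose in part. Of 24 scar matrix genes 14 rose (14 adjusted over the list alone; 3 with the series term, 12 with the sex term), with a median log2 change of 1.05. Fn1 rose 3.38-fold and Col3a1 by 1.94 on the log2 scale (1.27 without library 564, and 1.13 with the series term, adjusted p = 0.391), while Col1a1 (2.16-fold, adjusted p = 0.0712) and Col1a2 (1.75-fold, adjusted p = 0.083) did not pass, but did without library 376 (0.0265 and 0.0341). Pdgfrb was at 40.2 CPM ± 4.88 against 40.7 ± 5.51 in uninjured cord (adjusted p = 0.924). Of 17 matrix proteases and inhibitors 11 rose (11 adjusted over the list alone; 6 with the series term, 9 with the sex term), Timp1 23.0-fold (14.2-fold with the series term). Neuron markers fell in 16 of 20 cases (17 adjusted over the list alone; 4 with the series term, 14 with the sex term), Rbfox3 by 0.89, and beyond the list Grin2b fell by 2.38 (1.53 with the series term) and the glycine receptor subunit Glra1 by 1.79. Of 19 cholesterol genes 8 fell (8 adjusted over the list alone; 1 with the series term, 6 with the sex term). The muscle genes Ryr1 and Mybpc2 fell by 3.61 and 2.72 (1.80 and 1.46 without library 377), where uninjured libraries 377 and 385 carried muscle transcripts, and Ryr1 lost its call without library 377 (adjusted p = 0.116) or 549 (0.052). Nras rose 1.44-fold and Slc1a3 1.53-fold, and Hras1 did not pass (log2 -0.19, adjusted p = 0.208). The Nras call was lost without library 376 (adjusted p = 0.0768), 377 (0.0907), 513 (0.0868) or 564 (0.0632). Camera's adjusted p for scar matrix, proteases, neurons and cholesterol was 2.28e-05, 4.83e-05, 4.25e-06 and 0.00131, and 0.501, 0.36, 0.36 and 0.501 with an estimated correlation.

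In all, 8063 genes changed between tamoxifen lesions and uninjured cord, of which 355 had stepped counts (337 of these higher). Of the 8063, 4328 were higher and 3735 lower (edgeR quasi-likelihood, Benjamini-Hochberg threshold 0.05), 1673 by at least 2-fold. The count was 1951 with the series term (1244 higher), 2024 in the low series alone, 7219 with the sex term and 3540 without the libraries with muscle transcripts. Camera called 16 of 32 lists (14 up, 2 down), none with an estimated correlation, and other divisions of the 8 libraries gave up to 26. By fry 21 lists passed, 18 up and 3 down.

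Genes changed by injury mostly differed in the opposite direction between tamoxifen and vehicle lesions, a comparison in which the shared vehicle libraries alone give an excess. Of the 8368 injury genes, 75.1% had the opposite sign between tamoxifen and vehicle lesions (75.5% of those that rose, 74.7% of those that fell). When 2 vehicle libraries called the injury genes and the other 2 served as the reference for tamoxifen, the share averaged 73.4% over 6 splits, from 57.8% to 85.6%. In 20 simulations without a tamoxifen effect, with the vehicle libraries shared by both comparisons and genes drawn independently, the share was 56.5% on average (55.5% to 58.1%). Among the 2052 injury genes of at least 2-fold the share was 85.2%, and 80.0% on average over the 6 splits (82.5% of those that rose and 69.7% of those that fell). The lowest split called injury genes in libraries 402 and 429. No split was simulated, so the shares of the splits have no simulated level to be set against. Of the genes higher in vehicle lesions than in uninjured cord, 3044 were also higher in tamoxifen lesions, where independent calls would give 1154; of those lower, 2810 were also lower, where independent calls would give 901. With 2 uninjured libraries kept for each comparison, 2036 to 2231 higher and 1872 to 2060 lower genes were shared. Simulations without an injury effect shared 0, but they leave the effects out and do not show how much of the overlap the shared uninjured libraries give.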

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

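In this part, the tests on scar matrix genes and the test of library 452 on the genes with stepped counts were chosen only after the result was seen; the tests of shared sequence, of interferon genes in FPKM and of the divisions of the libraries were set before theirs. In 396 groups of 4 libraries (99 genes, 32 lists and the totals), a library stood apart from the other 3 in 27, by the gap to its neighbour against the range of the group; chance gives this in about 1 in 20 groups, or 20 of them.

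Uninjured library 467 was low in reactive astrocyte markers (mean log2 CPM 3.24 against 3.91 to 3.99), cytokines and chemokines (-0.197 against 0.305 to 0.374), C1s (0.790 CPM), Col4a1 (38.4), Col6a3 (9.66), Dcn (16) and Dpt (1.67), and high in Insig1 (183) and Ddx3y (103). Library 376 had a low total (8868865 counts, 8.87 as scaled for the test) and was high in Ccl21a (0.115 CPM) and Mmrn1 (0.344), and library 377 was high in Rbfox3 (206). The other uninjured libraries were at 0 for Ccl21a and Mmrn1, where any count above 0 sets a library apart. The same holds below for Ddx3y in 564 and Ccl21a in 452. Among vehicle lesions, 428 was low in Ltbp2 (14.1) and Tnn (1.36) and high in Stmn2 (320), and 429 was low in Ddx3y (0.276) and Glra1 (57.8). Among tamoxifen lesions, 564 stood apart in Ddx3y (0.0918 against 0). Library 452 was low in Cdk1 (3.00 CPM), Etv1 (56.9), Lgr6 (3.12), mt-Nd3 (1.92) and Sumo2 (2.04) and high in Cst7 (45.9), Glra1 (77.2) and Ccl21a (0.120). For mt-Nd3 and Sumo2 the counts of the other tamoxifen libraries stepped, and 452 was not low among the 9 libraries of the low series. Those lay at 0.251 to 1.93 CPM for mt-Nd3 and 1.13 to 2.05 for Sumo2, without TMM factors.

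Scar matrix genes were lower in tamoxifen than in vehicle lesions. Separate counting of the high series is argued against by the authors' FPKM, where the 24 members had a median difference of -2.41 (quartiles -3.03 and -1.54), and the members had a median of -2.74 in library 452 alone. A sex term left a median of -2.73 (quartiles -3.43 and -2.02; tamoxifen minus female vehicle library 429, -2.35), and a muscle score term left -1.85 (quartiles -2.55 and -1.07; tamoxifen minus vehicle library 428, which lacks muscle transcripts, -1.63), so neither may be the whole cause, although the muscle term brought the genes changed from 2655 to 99. A smaller share of meninges and nerve roots in the dissected piece stays open and is a candidate explanation: Schwann cell and nerve root genes had a median of -0.879 (quartiles -0.989 and -0.209, 12 genes; -0.774 with the series term). An effect of recombination on the scar also stays open, as does a difference in preparation between the sample name series, since 452 is a single library, and the lesions were described by their scarring. Recombination cannot be told apart from an effect of tamoxifen itself, since every mouse given the drug carried the alleles.

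Genes whose counts stepped in the high series were higher in tamoxifen lesions. Reads shared with near-identical copies, counted in the high series only, are a candidate explanation that the sequences go with: the 363 stepped-up genes with a share had a median of 44.8% of 31-base words in common with another gene (quartiles 16.4% and 82.7%), against 1.51% in 15525 others (permutation p = 1e-04, one-sided, the smallest that 10000 draws can give). A change that all tamoxifen lesions share would move counts and FPKM alike, so it would not give the step that defines these genes. Whether such a change adds to their rise cannot be told, since only library 452 decides. Over 299 stepped genes library 452 lay 0.0745 above the vehicle mean on the log2 scale (quartiles -0.0949 and 0.254), against 1.73 for the high series. For mt-Co3, counts were 2.55 to 4.82 CPM in the 9 libraries of the low series and 5990 to 6720 in the high series, while FPKM was 3290 to 4370 and 4470 to 5110.

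Interferon-stimulated and antigen presentation genes were higher in library 452 than in the other tamoxifen libraries. Separate counting is argued against, as FPKM showed a median difference of 1.35 over 32 genes (quartiles 0.741 and 1.93), and CPM 1.47. A difference between animals, or between preparation of the sample name series, was not tested and stays open, since 452 is the only tamoxifen library of its series. No biological explanation was tested, as the labels give 452 no separate group.

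Of the 35 divisions of 8 libraries into 4 and 4, the real one alone (1 of 35) gave as many changed genes in each comparison: 8755 against a highest other of 6 for vehicle against uninjured, 1513 against 2 for tamoxifen against vehicle, and 7487 against 1 for tamoxifen against uninjured, in fits of the 8 libraries. This is the smallest share that 35 divisions can give. The other divisions mix the groups, so group differences widen their spread and they do not show what chance alone gives. For tamoxifen against vehicle, the real division also kept the high series together and the males together. For lists called by camera with a preset correlation chance cannot be excluded either. There 10 of 35 divisions gave as many as the real 20 (highest other 24), 3 of 35 as many as 19 (highest other 19), and 17 of 35 as many as 16 (highest other 26). For tamoxifen against vehicle, the other divisions with 19 lists put 452 with vehicle 402, 429 and 457, which keeps the high series together on the other side, or 549 with the 3 male vehicle libraries, which keeps the males together; with the series term 20 lists were called and with the sex term 21.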

How the results depend on the processing

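In this part, the results for the low sample name series alone, for sex and series terms together, for female libraries, for stepped genes left out and for the libraries with muscle transcripts or their score were chosen after the result was seen, as were lists with a series or a sex term. No paired analysis was possible because mouse numbers are not shared among the groups. Over named genes and lists, 3822 gene results and 1730 list results kept their direction and side of the threshold under an alternative, 485 and 109 no longer passed, 11 and 39 newly passed, and 42 and 42 changed sign; the cause of these changes was not tested unless fewer libraries or a stricter fold give it. DESeq2 size factors, library totals, other filters, the DESeq2 Wald test, limma-voom and thinning left each count of genes within 1.5 times. Depth limits genes near the filter, and the text gives levels in place of a fold where the lower group averaged under 0.5 CPM.

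For vehicle against uninjured, 8368 genes became 2052 with a fold of at least 2, 5250 in female libraries and 296 without the 5 libraries with muscle transcripts; leaving out 1 library gave 7267 to 8987. For tamoxifen against vehicle, 2655 became 1518 and 1438 by limma on log2 FPKM with 1 and 0.1 added, 1513 in the 8 libraries, 989 with a sex term, 57 with a series term, 615 with a fold of at least 2, 29 in the low series, 38 with both terms, 204 in female libraries, 99 with a muscle score term, and 0 without the 5 libraries with muscle transcripts (edgeR; 1239 genes at an unadjusted p under 0.05), a setting run with no other tool; leaving out 1 library gave 1236 (513) to 4631 (452). For tamoxifen against uninjured, 8063 became 1951 with a series term, 1673 with a fold of at least 2, 2024 in the low series, 1522 with both terms and 3540 without muscle libraries; leaving out 1 library gave 6717 to 8895. Lists called became 0, 1 and 0 with an estimated correlation in the 3 comparisons in that order, and for tamoxifen against vehicle 8 by fry, 12 without muscle libraries and 11 with the muscle score. The reversed share of 75.1% became 85.2% over genes of at least 2-fold and 84.6% in the low series, a setting with no split or simulated value to set it against; leaving out 1 library gave 68.7% to 80.1%.

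Lists that changed sign are given by adjusted p. For vehicle against uninjured these were ERK pathway genes by fry (0.55), with a series term (0.904), without muscle libraries (0.723) and when 1 library was left out (0.739 to 0.998 over all), myelin genes with a sex term (0.988), bone, cartilage and fat without muscle libraries (0.338), skeletal muscle with its own score (0.705), and erythrocyte markers when 1 library was left out (0.489 to 0.741). For tamoxifen against vehicle with a series term these were proliferation (1.84e-07, downward), antigen presentation (5.09e-07, upward), interferon-stimulated genes (1.7e-16, upward), ERK (0.476), oligodendrocyte precursors (0.0805), lymphocytes (0.121), and cytokines, axon growth inhibitors and erythrocytes (0.887 each). Without muscle libraries they were proteoglycans (0.92), ERK (0.904), microglia (0.905), lymphocytes (0.905), antigen presentation (0.92), interferon (0.177), ependymal (0.862) and bone, cartilage and fat (0.862). With the muscle score they were myelin (0.62), ependymal (0.757) and skeletal muscle (0.551). Leaving out 1 library changed the sign of interferon genes (0.0178 to 0.842), oligodendrocyte precursors (0.181 to 0.938) and proteoglycans (0.205 to 0.927). For tamoxifen against uninjured these were proteoglycans (0.818), ERK (0.699) and erythrocytes (0.54) with a series term, skeletal muscle (0.101) and erythrocytes (0.872) without muscle libraries, and when 1 library was left out fibroblasts (0.137 to 0.972), ERK (0.68 to 0.979), neutrophils (0.128 to 0.984) and Schwann cells (0.213 to 0.966).

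Genes that changed sign are given by log2 change. Hras1 in vehicle against uninjured was at 0.0194 and 0.0232 by limma on FPKM with 1 and 0.1 added. For tamoxifen against vehicle, Hras1 was at 0.0246 after thinning, 0.162 with a series term, 0.163 in the low series, 0.104 with both terms, 0.0535 without muscle libraries, 0.133 with the muscle score and -0.079 to 0.0331 when 1 library was left out, and Nras at 0.0266 without muscle libraries and -0.133 to 0.114 when 1 library was left out. With a series term, in the low series and with both terms, Slc1a3 was at -0.0111, -0.0103 and -0.0612 (and -0.00396 in females), Gfap at -0.133, -0.132 and -0.17, Mki67 at -0.963, -0.962 and -1.37 (and -0.117 with the muscle score), Arg1 at -1.36, -1.36 and -1.87, and Pcna at -0.00472, -0.00414 and -0.146. Cd68 was at 0.0439 without muscle libraries. For tamoxifen against uninjured, Pdgfrb was at 0.0457 and 0.0532 by limma on FPKM, 0.172 with a series term, 0.171 in the low series, 0.151 with both terms, 0.0267 without muscle libraries, 0.0491 with the muscle score and -0.111 to 0.0558 when 1 library was left out.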

Other observations

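Several lists outside the account above differed between lesions and uninjured cord. Oligodendrocyte precursor markers rose in 8 of 13 cases in vehicle lesions and 7 of 13 in tamoxifen lesions against uninjured cord (8 and 7 adjusted over the list alone; for tamoxifen 0 with the series term and 7 with the sex term; camera adjusted p = 0.0353 and 0.00504, the first 0.0588 without library 429, and adjusted p of 0.569 and 0.501 with an estimated correlation). Endothelial markers rose in 9 of 16 and 5 of 16 cases (10 and 4 adjusted over the list alone; for tamoxifen 2 with the series term and 4 with the sex term; camera adjusted p = 0.00968 and 0.0329, the second 0.0979 without library 467, 0.223 without 452 and 0.0886 without 564, and adjusted p of 0.447 and 0.501 with an estimated correlation), and the endothelial genes Tie1 and Cdh5 fell by 0.47 and 0.69 on the log2 scale from vehicle to tamoxifen lesions, 2 of 16 (2 adjusted over the list alone; 0 with the series term and 0 with the sex term; camera adjusted p = 0.304). Cdh5 lost its call without library 457 (adjusted p = 0.0513) or 513 (0.0521). Immediate early and heat shock genes rose in 7 of 14 cases and fell in 2 in vehicle lesions (7 and 2 adjusted over the list alone; camera adjusted p = 0.0315, 0.0682 without library 428, and adjusted p = 0.131 with an estimated correlation), and 3 of 14 fell from vehicle to tamoxifen lesions (6 adjusted over the list alone; 0 with the series term and 2 with the sex term; camera adjusted p = 0.0292, 0.0787 without library 428 and 0.171 without 452, and adjusted p = 0.229 with an estimated correlation).

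Molecules that act on axon growth went both ways. Of 19 axon growth inhibitory genes 5 rose and 7 fell in vehicle lesions against uninjured cord (5 and 8 adjusted over the list alone; camera adjusted p = 0.457), and 2 rose and 1 fell from vehicle to tamoxifen lesions (2 and 1 adjusted over the list alone; 0 with the series term, 1 rose and 0 fell with the sex term; camera adjusted p = 0.453). Of 14 neurotrophic and growth-permissive genes 7 rose and 2 fell in vehicle lesions (8 and 2 adjusted over the list alone; camera adjusted p = 0.0925). Of 17 myelin genes 5 rose in vehicle lesions (1 adjusted over the list alone, camera adjusted p = 0.546), but with the sex term 1 rose and 2 fell. Of 9 ependymal genes 2 fell (0 adjusted over the list alone, 3 with the sex term, camera adjusted p = 0.335). Of 4 measured lymphocyte markers 2 rose (2 adjusted over the list alone; camera adjusted p = 0.237), of 9 neutrophil markers 2 rose (1 adjusted over the list alone; camera adjusted p = 0.0925, but 0.00129 without uninjured library 376, the highest of its group in this list, and 0.049 without 457, and adjusted p = 0.569 with all libraries and an estimated correlation), and of 7 erythrocyte markers none passed (0 adjusted over the list alone; camera adjusted p = 0.657).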
